A study of Hordeum vulgare with 2 samples.

How the data were processed

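The data are peptide tables from isotope-coded affinity tag (ICAT) experiments on protein extract from dissected embryos of the malting barley cultivar Barke, germinated for 48 h. ICAT reagents are thiol-reactive tags that exist in a light and a heavy form, so that the same cysteine peptide from 2 labelled extracts appears as a pair of peaks whose intensity ratio is read in 1 mass spectrum. Per the labels, free thiols were alkylated with iodoacetamide (IAM) during extraction, and portions of the extract were then kept for 1 h with or without thioredoxin (Trx), a small protein that reduces disulfide bonds in other proteins. In the sample called the blocked run here, IAM was given again, at 10 mM, so that cysteines freed by Trx could no longer take up the tag. All remaining cysteines were then reduced chemically and tagged, light for the arm with Trx and heavy for the arm without it, and the arms were combined in equal parts. The control run went through the same steps with no IAM after the incubation. A cysteine reduced by Trx therefore loses light tag in the blocked run and gives a heavy/light ratio above 1, while in the control run it is tagged in both arms.

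Per the labels, combined extracts were digested with trypsin, tagged peptides were captured on avidin, and they were measured by liquid chromatography and tandem mass spectrometry on a QSTAR instrument. Peak lists were made with the Mascot script 1.6b20 for Analyst QS 2.0, per the series description. The same source gives a Mascot search of the green plant part of Swiss-Prot 54.6, of a public non-redundant protein collection and of the barley gene index (HvGI) 9.0, with mass tolerances of 0.2 Da and no missed cleavage. It also states that MSQuant 1.4.3a12 gave the ratios, that spectra were inspected by hand, and that matches were kept from a Mascot score of 20 and a sequence tag of 3 residues. The deposited heavy/light ratio of each peptide is the authors' average of the ratios measured for that peptide, and the authors' SD beside it is in the same ratio unit. The number of ratios behind each average is not given in the sources used here, nor is any centring of the ratios. The authors' SD is listed as 0 for 27 peptides of the blocked run and 10 of the control run, and these zeros were not read as an absence of error, so checks of SD ranges left such peptides out. The deposited score is the Mascot ion score of the match. Other deposited columns (charge, measured mass and mass error) were used only to describe the runs. Mean charge was 2.60 in the blocked run and 3 in the control run. Median measured mass was 1600 and 1764 Da, and median mass error -0.605 and 1.83 ppm.

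Each group has 1 sample, so the difference between the runs has no replicate check, no p-value was computed, and peptides are not replicates of the comparison. Bootstrap intervals given with the further observations resampled peptides 2000 times as if independent, so they cover the choice of peptides within these samples and not variation between samples. The text labels describe both samples as incubated with and without Trx, while the source name of the control calls it untreated with Trx. The fuller description was followed, and if the control had received no Trx in either arm it would still measure the spread of the ratio without a block.

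Each peptide sequence occurs once per run (199 in the blocked run and 93 in the control run), and ratios were taken to log2. The limits were the control mean ± 2 SD of log2 ratio over its peptides, which is 0.822 to 1.24 as a ratio. Peptides of both runs were counted above, within and below these limits, with exact Clopper-Pearson 95% intervals of the shares, which treat peptides as independent and cover counting only. Because the control set the limits, its own count outside them is small by construction. For peptides in both runs, the log2 ratio of the control was subtracted from that of the blocked run, and the authors' SD ranges (ratio ± SD) were checked for overlap where both SDs were above 0. The apparent share of label lost in the Trx arm was computed per peptide, whatever its number of cysteines, as 100 × (1 − light/heavy). For entries with 2 or more peptides, the span between their peptides was computed on the log2 scale. Correlations across peptides are descriptions of these runs, since peptides are not independent replicates.

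Protein lists were fixed as word patterns on the deposited protein names before the data were examined: redox; carbon metabolism; translation; folding and proteolysis; defence and inhibitors; storage and late embryogenesis; amino acid and nucleotide metabolism; cytoskeleton and signalling; and, as markers of material other than embryo, proteins of other seed tissues. A list's median was placed among the medians of 10000 random sets of as many peptides from the same run. These percentiles describe the run and are not tests. The name patterns also took in a 2-dehydro-3-deoxyphosphooctonate aldolase and an allyl alcohol dehydrogenase under carbon metabolism, and an alpha-amylase inhibitor under other seed tissues. Proteins deposited under other names were left out. Thaumatin-like proteins were meant for the defence list, but the pattern missed the thaumatin-like protein Barperm1, whose peptides are in no list. Many names come from database entries of other plants, so they give the closest named protein and not a barley gene. Genomic positions of the peptides were not analysed here.

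The peptides named were chosen by a rule fixed beforehand. It took the 25 highest and 5 lowest ratios of the blocked run, the 2 highest and 2 lowest of each list, shared peptides outside the limits in the control run, the 5 shared peptides with the largest and the 5 with the smallest difference between the runs, and the 5 entries with the widest span. A peptide named outside this rule is said to be so where it appears.

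The counting step was tested on simulated runs drawn from the control spread, with 199 peptides of which 100 were changed. It recovered 58.2% of peptides set to a ratio of 1.25, 97.8% at 1.5 and 100% at 2, and placed 2.18% to 2.77% of unchanged peptides above the limit. Unchanged peptides were given the control mean and SD, with no offset between the runs. In the data, shared peptides within the limits had a median log2 difference of 0.15, about the control SD of 0.147. The simulated rates would not hold for a run with such an offset. The authors' SD, in ratio units, had a median of 0.09 in the blocked run and 0.06 in the control run. Its maximum was 0.39 and 0.17. A wider error in the blocked run was not simulated and could also change these rates. Alternatives planned before the data were examined were limits of 3 SD, a median with scaled median absolute deviation, fixed ratios of 1.5 and 2, the highest and lowest control peptide, a score of at least 40 and peptides with 1 cysteine (both applied to the control run and its limits too), centring on the control median, each entry on its own, 1 value per protein, shared peptides only, and means in place of medians. Alternatives chosen after seeing the data were limits without the 2 highest control peptides, leaving out peptides with an SD of 0, the ratio minus its SD against the limit for peptides with an SD above 0, lists by the protein names of either run, the score and 1-cysteine choices with the limits of all control peptides, and division of the blocked run by the median difference of shared peptides within the limits. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.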

Results

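Cysteine peptides of germinated barley embryo extract were compared between an ICAT run with an IAM block after thioredoxin and a control run without it, to find cysteines that thioredoxin reduced. The blocked run gave 199 peptides from 163 protein entries, with Mascot scores of 20 to 118 (median 41). The control run gave 93 peptides from 73 entries, with scores of 21 to 90 (median 39). Each run is 1 sample, so values below carry the authors' SD within the run (±) and no replicate error, and differences between the runs describe these 2 samples only. The number of spectra behind each ratio is unknown.

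The first comparison asked which cysteine peptides carried less light label, the label of the Trx arm, once Trx-reduced thiols had been blocked. The highest ratio belonged to dehydroascorbate reductase, which regenerates ascorbate from its oxidised form, at 2.64 ± 0.27. It was followed by the glycolytic enzyme enolase at 2.46 ± 0.29, alcohol dehydrogenase 1, the last enzyme of ethanol fermentation, at 2.11 ± 0.14, and a Bowman-Birk trypsin inhibitor, from a family of disulfide-rich protease inhibitors, at 2.01 ± 0.39. A zinc-binding oxidoreductase stood at 2.01 ± 0.35. These were the 5 peptides with an apparent loss of over 50% of the label in the Trx arm. The enolase peptide holds 2 cysteines and the Bowman-Birk peptide 3, so their values are not a loss per cysteine. In the control run dehydroascorbate reductase also had a high ratio, 1.34 ± 0.14, while the other 4 leading peptides were not among the shared peptides.

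Of the 199 peptides in the blocked run, 101 lay above the control limit of 1.24 (50.8%, 95% interval 43.6% to 57.9%), 98 lay within the limits and 0 lay below 0.822 (at most 1.84%). The same limits left 2 of 93 control peptides above (2.15%, 0.262% to 7.55%) and 0 below. The median ratio was 1.249 with the block and 1.01 without it, and the 10th to 90th percentiles were 0.994 to 1.75 and 0.886 to 1.15. Over the 101 peptides the median apparent loss of light label was 35.9%, with a range of 19.5% to 62.1%. A fixed limit of 1.5 left 65 peptides above and a fixed limit of 2 left 5, against 0 control peptides for each.

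**Figure D1:**
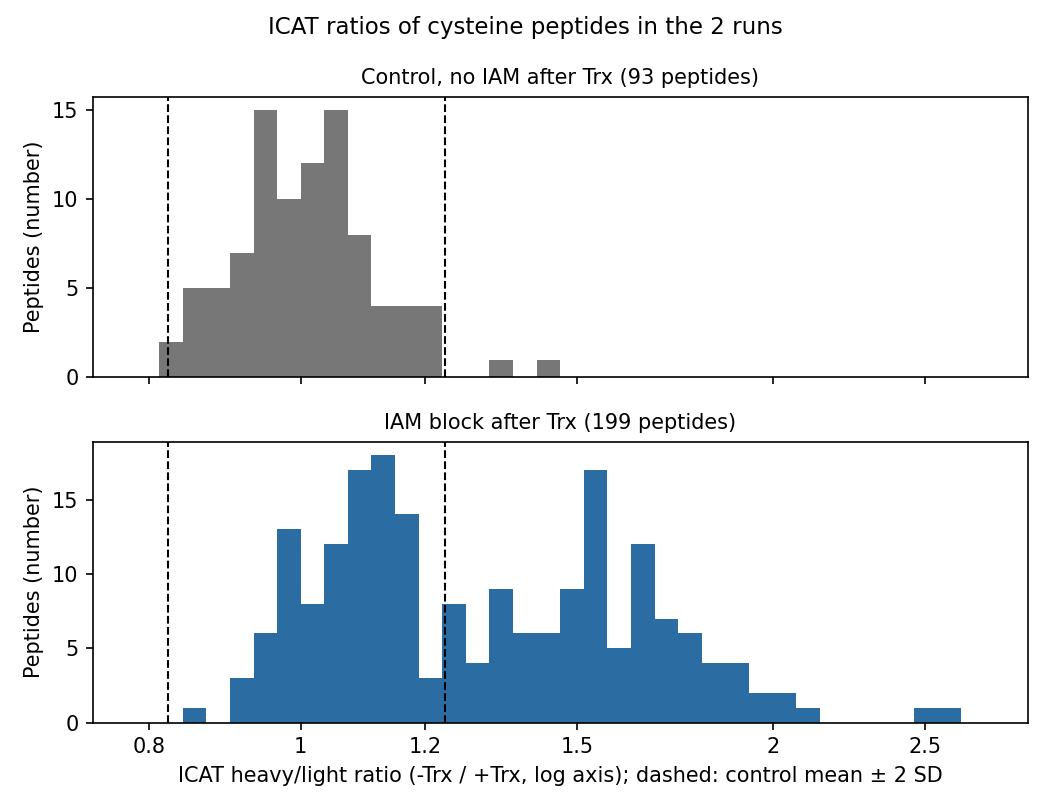
Number of cysteine peptides by ICAT heavy/light ratio (log axis) in the control run (93 peptides, top) and in the run with the IAM block after Trx (199 peptides, bottom). Dashed lines are the control mean ± 2 SD (0.822 and 1.24); 101 peptides lie to the right of the upper line with the block and 2 without it.

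The rest of the 25 highest ratios covered several kinds of protein. Non-specific lipid transfer protein 1, a small disulfide-bonded protein, had 1.98 for its peptide QTVCNCLK, and adenosylhomocysteinase, which splits the by-product of methyl transfer, had 1.94, each with an SD listed as 0. B1 hordein, a storage protein of the starchy endosperm, had 1.92 ± 0.14. Cyclophilin A-2, a peptidyl-prolyl isomerase, had 1.904 ± 0.19 and 1.808 for its peptides. Dihydrolipoyl dehydrogenase, the flavoprotein of the 2-oxoacid dehydrogenase complexes, had 1.89, and 1-Cys peroxiredoxin PER1, an embryo and aleurone peroxiredoxin, had 1.85 ± 0.11. An avenin-like protein had 1.83 ± 0.19, the alpha 1 subunit of succinyl-CoA ligase, a citric acid cycle enzyme, 1.78 ± 0.17, and embryo globulin 1.77. S-adenosylmethionine synthetase 1 had 1.76 ± 0.09, an IN2-1 protein 1.75 ± 0.12, an aluminum-induced protein 1.74 ± 0.05 and a pyruvate kinase-like protein 1.73. A hypothetical protein (1.92 ± 0.12) and 2 rice-annotated entries, Os12g0235800 (1.77 ± 0.23) and Os03g0277300 (1.71 ± 0.19), were also among them, and the others are given with their groups or with the spread within proteins. The lowest ratios were those of an unnamed product at 0.863 ± 0.13, embryo-specific protein Ose731 (peptide QCLIFDGPDAGAR) at 0.923 ± 0.11, a glyoxalase family protein at 0.932 ± 0.05, an r40c1 protein at 0.932 ± 0.01 and Os01g0749000 at 0.942 ± 0.04.

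Among the lists of proteins, translation stood highest by its place among random sets. Of its 32 peptides 24 lay above the limit, and its median of 1.51 was at percentile 99.3 of random sets of the same size. Ribosomal proteins made up most of this, with 22 of 26 peptides above the limit and a median of 1.54. L4 had 1.84 and S26 1.73 ± 0.1, while S24 had 0.983 ± 0.07. Translation factors and tRNA synthetases had 2 of 6 peptides above, and elongation factor 1-gamma 2, a subunit of the factor that recharges EF-1A with GTP, had 1.07 ± 0.08. In the control run the list's 13 peptides all lay within the limits, yet their median of 1.06 was also high in that run, at percentile 94.0.

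Folding and proteolysis lay at the other end, with 5 of 20 peptides above the limit and a median of 1.0985 (percentile 1.15; control 0.993, percentile 37.2). All 6 proteasome peptides lay within the limits, at 0.972 to 1.05, among them alpha type 1 at 0.972 and 0.988 ± 0.05. The cyclophilins divided, with 2 of 4 peptides above. Carbon metabolism also lay low, with 7 of 20 peptides above and a median of 1.12 (percentile 3.60; control 0.958, percentile 7.77), although it held enolase and alcohol dehydrogenase 1. Its lowest members were cytosolic malate dehydrogenase at 0.969 ± 0.09 and 2-dehydro-3-deoxyphosphooctonate aldolase at 0.987 ± 0.09, an enzyme of cell wall sugar synthesis outside central metabolism. With the 106 peptides scoring at least 40 only, the medians were close to these, 1.55 for translation (17 peptides, percentile 97.3) and 1.098 for folding and proteolysis (12 peptides, percentile 4.16), and neither list stood outside the central 95% of random sets.

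Defence proteins and inhibitors had 11 of 14 peptides above the limit, against 1 of 3 in the control run. Their median of 1.504 was at percentile 93.6, and their control median of 0.99 at percentile 44.9. Barperm1, which the name pattern missed, is not in these counts and had 1 of 3 peptides above in the blocked run. In the blocked run the defence list's 6 peptides with several cysteines had a median of 1.67. The list's 8 peptides with 1 cysteine had 5 above and a median of 1.33 (percentile 69.1 among peptides with 1 cysteine). With a score of at least 40, 5 of the list's 7 peptides lay above (percentile 56.4). Lipid transfer proteins gave 7 of 8 peptides above and Bowman-Birk inhibitors 3 of 4. The lipid transfer peptides include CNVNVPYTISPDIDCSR, which also lay above the limit in the control run. The lowest members were CNVNLPYK of a lipid transfer protein at 0.994 ± 0.08 and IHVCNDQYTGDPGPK of the Bowman-Birk inhibitor at 1.13 ± 0.02. Amino acid and nucleotide metabolism had 8 of 10 peptides above, with a median of 1.4795 (percentile 88.3; control 1.09, percentile 96.9). Adenosylhomocysteinase and S-adenosylmethionine synthetase 1, enzymes of the methionine cycle, were its highest members, and glutamate dehydrogenase (1.18 ± 0.11) and the aminotransferase AGD2 (1.01 ± 0.09) lay within the limits.

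The redox list had 6 of 9 peptides above the limit in the blocked run, against 1 of 6 in the control run. Its median of 1.29 lay close to the middle of random sets (percentile 57.8), and its control median of 1.07 at percentile 94.5. Dehydroascorbate reductase and PER1 were highest, and the peptides deposited under the name glutathione S-transferase had 1.09 and 1.08 ± 0.04. With the blocked run divided by the 1.11-fold median difference of shared peptides within the limits, a choice made after seeing the data and an offset kept small by taking peptides of low blocked ratio, 3 redox and 4 carbon metabolism peptides lay above. Stricter limits chosen beforehand did much the same, with 3 and 4 above for limits of 3 SD, 3 and 3 above the highest control peptide, and 2 and 3 above a fixed ratio of 1.5. Storage and late embryogenesis proteins had 4 of 7 above and a median of 1.49 (percentile 82.2; control 1.06, percentile 88.9), with B1 hordein and PER1 high and globulin 2 at 0.99 ± 0.15 and 1.04. Neither of the 2 peptides under cytoskeleton and signalling, a Ran-binding protein at 1.17 ± 0.09 and a Rab GTPase-activating protein at 0.958 ± 0.11, lay above the limit (percentile 10.0). In the control run the list held the same Ran-binding peptide and SCLLLR of a Ras-related protein (median 0.883, percentile 1.91). SCLLLR has another name in the blocked run, where it had 1.44 ± 0.07, so that by the names of either run, a choice made after seeing the data, 1 of the list's peptides lay above. Proteins of other seed tissues were also present, with 3 of 4 peptides above: B1 hordein, beta-amylase (1.65 ± 0.03, with a further peptide at 1.11 ± 0.05) and alpha-amylase inhibitor BDAI-1 (1.65 ± 0.19). Their median was 1.65 (percentile 96.2), and 1 control peptide had 1.08. B1 hordein thus belongs both to the storage list and to these markers of non-embryo tissue, and BDAI-1 both to them and to the defence list.

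**Figure D2:**
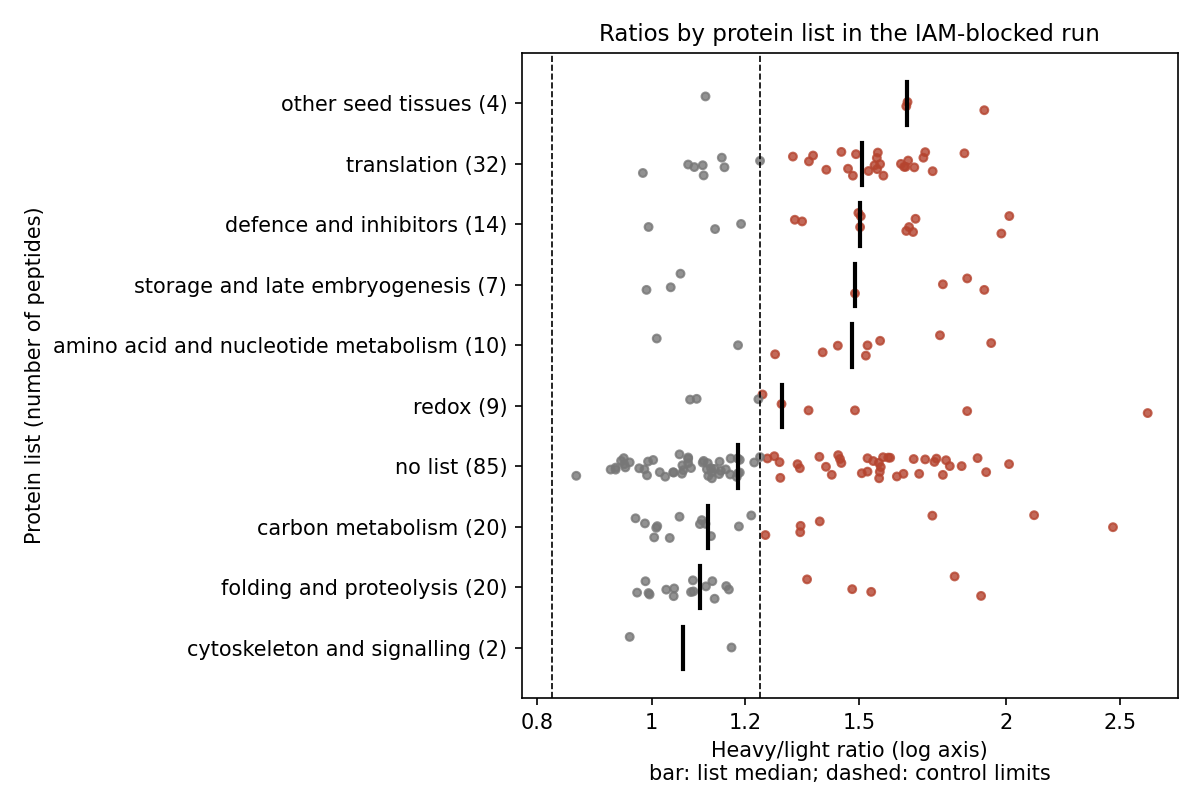
Heavy/light ratio (log axis) of each peptide of the blocked run by protein list, with the number of peptides in brackets; black bars are list medians, dashed lines the control limits, red points lie above the upper limit and some peptides belong to 2 lists. Translation has 24 of 32 peptides above the limit and folding and proteolysis 5 of 20.

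The second comparison set each cysteine peptide against itself, with and without the block. Dehydroascorbate reductase had the largest difference, 1.97-fold. Cold shock protein-1, from a family of nucleic acid-binding proteins, followed at 1.87-fold (1.56 against 0.835), then cyclophilin A-2 peptide SGICSK at 1.803-fold (1.81 against 1.00), ribosomal protein S11 at 1.79-fold (1.64 ± 0.16 against 0.913 ± 0.04) and embryo globulin at 1.67-fold (1.77 against 1.06). At the other end were aspartyl aminopeptidase at 1.01-fold, the large subunit 1 of ADP-glucose pyrophosphorylase, an enzyme of starch synthesis, at 1.02-fold, triosephosphate isomerase at 1.02-fold, inositol monophosphatase 3 at 1.03-fold and a hypothetical protein at 1.03-fold. The authors' SD ranges overlapped for each of these 5. Among the 5 largest differences, the ranges were apart for dehydroascorbate reductase and S11. Cold shock protein-1, SGICSK and embryo globulin have an SD listed as 0 in both runs, so their error is unknown.

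Over the 82 peptides in both runs, the median difference was 0.31 on the log2 scale (1.24-fold, SD 0.25 across peptides). The ratio was higher with the block for 81 of them, and the exception was the glyoxalase family peptide LAYIVCYVK (0.932 ± 0.05 against 1.05 ± 0.07). Of the 69 peptides with an SD above 0 in both runs, 43 had SD ranges apart, all higher with the block, and 26 had overlapping ranges. The 42 shared peptides above the limit in the blocked run had a median difference of 1.47-fold, and ranges were apart for 32 of the 35 with such SDs. The 40 within the limits had a median difference of 1.11-fold, with ranges apart for 11 of 34. These 2 sets were divided by the blocked ratio itself, so part of the gap between them follows from the division. Apparent label loss had a median of 35.7% for the 42 peptides with the block and 5.75% for the same peptides in the control run. Because the 42 were picked by a high blocked ratio, part of this gap, and of the 32 ranges apart, follows from that choice too.

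Both control peptides outside the limits were shared. Besides dehydroascorbate reductase this was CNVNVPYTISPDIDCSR of lipid transfer protein 1, which had 1.498 ± 0.17 with the block and 1.42 ± 0.11 without it, so that its place above the limit was not specific to the block. Ratios of shared peptides also went together between the runs, with r = 0.62 and rho = 0.62 across peptides, r = 0.60 without the 2 farthest control values and r = 0.63 over 73 protein means. A further 117 peptides, 59 of them above the limit, had no control value of their own.

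**Figure D3:**
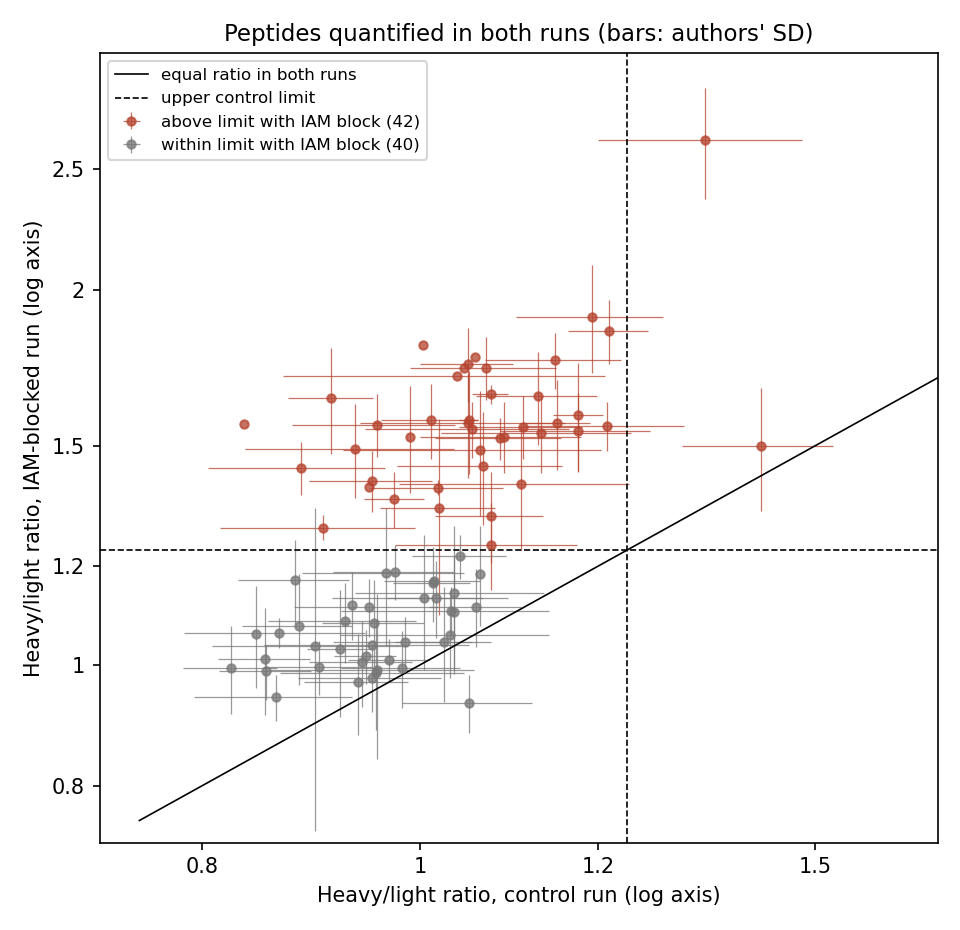
Heavy/light ratio with the IAM block against the control ratio (both log axes) for the 82 peptides in both runs, with the authors' SD as bars (a listed SD of 0 shows no bar). Red points are the 42 peptides above the upper control limit of 1.24 with the block (dashed line); 81 of 82 points lie above the line of equal ratios.

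The third comparison asked whether cysteines of the same protein differed. Embryo-specific protein Ose731 had the widest span on the log2 scale, from 0.923 ± 0.11 to 1.79 ± 0.38 (peptide QDLADCVER). Enolase (ENO_ORYSJ) ranged from 1.34 ± 0.24 for SCNALLLK to 2.46 ± 0.29 for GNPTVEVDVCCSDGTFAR, which holds 2 cysteines, with all 3 of its peptides above the limit. The Bowman-Birk inhibitor ranged from 1.13 ± 0.02 to 2.01 ± 0.39, a lipid transfer protein from 0.994 ± 0.08 to 1.65 ± 0.14, and Barperm1, a barley thaumatin-like protein, from 1.00 ± 0.09 to 1.51 ± 0.36. Of 27 entries with 2 or more peptides, 10 had all peptides above the limit and 9 had all within. The other 8 had peptides on both sides. SD ranges of the lowest and highest peptide were apart for 6 of these and overlapped for 1, and 1 had an SD listed as 0. In 4 of the 5 widest entries the highest peptide holds several cysteines. Among peptides with 1 cysteine, 6 entries had peptides on both sides of the same limit, a choice made after seeing the data, and 5 with the limit taken from control peptides with 1 cysteine.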

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

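The 7 alternatives named as added below were chosen after seeing the data, the others before. Of the alternatives for main results, 65 stayed within 1.5 times the reported count, or within the spread of the reported value, and 21 did not. A direction turned in 0 of them, but only the median blocked ratio and the median shared difference could have turned. The count of 0 peptides below the limits, also among the 65, could not move under wider limits. The 65 include 9 from centring on the control median, which could move no count, and leave out taking each entry on its own. The count of 101 peptides above the limit was 83 with limits of 3 SD, 106 with a scaled median absolute deviation and 77 above the highest control peptide. With 1 value per protein, 85 of 163 entries lay above, a share close to the 101 of 199. Higher fixed limits left fewer by construction. A ratio of 1.5 left 65 peptides in the blocked run and 0 in the control, and a ratio of 2 left 5 and 0, with a median apparent loss of 52.7% and 2 proteins with peptides on both sides in place of 8. Fewer peptides entered under 3 of the choices made beforehand, and 2 of these also set new upper limits, 1.27 for the score and 1.22 for 1 cysteine. With a score of at least 40 there were 55 above of 106 (58 with the limits of all control peptides, added), 3 proteins with peptides on both sides (3 with those limits) and 0 lists outside the central 95% of random sets, against 2. Shared peptides alone gave 42 of 82, and peptides with 1 cysteine gave 5 proteins with peptides on both sides (6 with the limits of all control peptides, added). The control count of 2 became 1 with 3 SD or with 1 cysteine under either limit, 0 against its own highest peptide, and 5 without the 2 highest control peptides (added), which narrows the limits. Taking each entry on its own and centring on the control median could move no count, since each sequence occurs once and centring shifts both runs and the limits together.

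Dividing the blocked run by the 1.11-fold median difference of shared peptides within the limits (added) left 82 peptides above and 1 below. Those shared peptides were picked by a low blocked ratio, so the offset is small by construction. It gave a median log2 ratio of 0.17 and a median shared difference of 0.16. It took the redox list from 6 to 3 peptides above and carbon metabolism from 7 to 4, while translation had 21 in place of 24. Leaving out peptides with an SD listed as 0 in both the counts and the limits (added) left 82 above, and 71 of the 172 peptides with an SD above 0 stood above the limit by more than their SD (added). Lists by the names of either run (added) left 2 lists outside the central 95%, as before. List values stayed within the same bounds under 108 alternatives, 16 of them from centring, and left them under 28, of which 26 were lower. The number of spectra per ratio, which sets the precision of each value, is unknown.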

Other observations

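The peptides, pairs and tests in this part were chosen after the values were seen, except the tests of the identified label form, of several-cysteine peptides and of cysteine surroundings, which were set out before their values were known. Peptides in no list made up 85 of the 199 in the blocked run, and 37 of them lay above the limit (median 1.18). They included proliferating cell nuclear antigen, the sliding clamp of DNA replication, at 1.69 ± 0.15, fructose-1,6-bisphosphatase 2, a gluconeogenic enzyme, at 1.59 ± 0.16 (control 1.18 ± 0.03), a regulatory A subunit of protein phosphatase 2A at 1.57 ± 0.13 (control 1.15 ± 0.04), a dihydroorotate dehydrogenase of pyrimidine synthesis at 1.53 ± 0.16, and spermidine synthase 1, of polyamine synthesis, at 1.41 ± 0.08 (control 0.952 ± 0.06). Ras-related protein RIC1, a small GTPase whose peptide has another name in the control run and falls under cytoskeleton and signalling there, had 1.44 ± 0.07 against 0.885 ± 0.08 in the control. By ratio, 38 peptides of the blocked run lay from 1.1 to below 1.2, 13 from 1.2 to below 1.3, and 24 from 1.5 to below 1.6.

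Near-identical peptides with a cysteine at the same place did not always have like ratios. There were 6 such pairs in the blocked run, of equal length with at most 4 differing residues, and for 3 the authors' SD ranges were apart. The cyclophilin peptides VIPDFMCQGGDFTR and IIPGFMCQGGDFTR, which differ at 2 residues, had 1.904 ± 0.19 and 1.08 ± 0.11. In the control run VIPDFMCQGGDFTR already had 1.193 ± 0.09, and IIPGFMCQGGDFTR was not among the shared peptides. ELESLCNPIISK of Os03g0277300 and ELEGICNPIIAK of a heat shock cognate protein had 1.71 ± 0.19 and 1.085 ± 0.11. LPGFHVCVGSGGER, named as monodehydroascorbate reductase, and LPGFHTCVGSGGQR of Os08g0151800 had 1.36 ± 0.07 and 1.07 ± 0.11, with control ratios of 0.974 ± 0.03 and 0.883 ± 0.05. The other 3 pairs, from S24, CPN60-1 and a 60S ribosomal protein with an entry annotated as a retrotransposon protein, had overlapping ranges.

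Nearly all shared peptides had higher ratios with the block, including 39 of the 40 within the limits. Unequal mixing of the arms would move all peptides by 1 factor and leave their spread, but the SD of log2 ratio over the 82 shared peptides was 2.13 times that of the control (bootstrap 95% interval over peptides 1.79 to 2.53). In these 2 samples this argues against mixing as the whole cause of the ratios above the limit. The interval covers the choice of peptides only, and how far this spread varies between samples is unknown. Smaller protein amounts in the Trx arm would appear in the control run as well, so that the runs should not differ, yet the median log2 difference over all 82 shared peptides was 0.31. This counts against it only if the control's light arm held Trx, which 1 label puts in doubt, so it stays open. For the 40 peptides within the limits, a small mixing offset was not separated from a slight reduction by Trx, and both stay open. Reduction by Trx, the explanation the design gives, stays open for the higher ratios and has no replicate.

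Shared peptides with high blocked ratios also had higher control ratios. A bias tied to the form of the tag that was identified would, as the only cause, leave no relation among peptides identified by opposite forms in the 2 runs. Yet r was 0.45 over these 36 peptides (0.16 to 0.68), against 0.74 over the 46 identified by the same form. This argues against such a bias as the only cause in these 2 samples. A part played by it was not tested, and blocked ratios differed by identified form, as given at the end of this part. IAM left from the extraction may have blocked some Trx-reduced cysteines in the control, for which r among the 42 peptides above the limit should stay positive, as it did at 0.43 (0.10 to 0.68). An error peculiar to each peptide may also be shared by both runs, in which case r should stay positive within the limits too, as it did at 0.41 (0.11 to 0.66). Both remain open, as does a part played by the identified form, and no biological explanation was tested.

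The 13 peptides with several cysteines had a median ratio of 1.67 in the blocked run, at percentile 99.9 of random sets, and 10 lay above the limit, against 91 of 186 with 1 cysteine (median 1.23). If label loss at each cysteine multiplied, the median log2 ratio per cysteine would be no higher than the 0.30 of peptides with 1 cysteine, and it was 0.36, with an interval of 0.29 to 0.42 that includes this value. Membership of the defence list cannot be told apart from the number of cysteines, because only 7 such peptides lay outside it, with a median of 1.508 (1.06 to 1.83) against 1.23 for 1 cysteine. That median is the value of FGGDTYCCR of Barperm1, a thaumatin-like protein that the name pattern of the defence list missed. In the control run 3 such peptides had a median of 1.13. No biological explanation was tested.

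A hypothesis was that cysteines with hydrophobic surroundings are over-represented above the limit. Over peptides with 1 cysteine, the mean Kyte-Doolittle hydropathy within 2 residues was -0.64 above the limit (91 peptides) and -0.25 within it (95), a difference of -0.39 (bootstrap 95% interval -0.76 to -0.0023), so it went the other way. A further hypothesis was that basic residues, which may lower a thiol's pKa, are more common within 3 residues. Their mean number was 0.88 above the limit and 0.73 within, a difference of 0.15 with an interval of -0.018 to 0.32, which leaves it undecided. For both measures only the peptide and at most 1 flanking residue on each side were known, so windows were shorter near a peptide end. Trypsin cuts after K or R, so both measures also depend on the cysteine's place in the peptide, which was not examined. These intervals, like the others in this part, run over peptides and say nothing of replicate samples. Separately, peptides of the blocked run identified by the heavy form had a median ratio of 1.39 (119 peptides) and those identified by the light form 1.15 (80), against 1.02 and 0.985 in the control.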
